A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

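Okazaki fragments of Saccharomyces cerevisiae in asynchronous culture had been sequenced in 5 samples, and each sample came as a fitted model of replication. Per the labels, 2 samples are replicates of strain yIW160 (wild type A and B, paired-end Illumina reads). Strain yIW160-SSDDCS, which overexpresses 6 replication initiation factors in galactose, gave 2 replicates in galactose (E and G) and 1 sample in glucose (F), all single-end Ion Torrent reads. The growth notes of all 5 samples give 30 degrees and doxycycline at 40 micrograms per ml for 2.5 hours. Those of the 3 yIW160-SSDDCS samples add 4 hours in 2% of the sugar before it. The medium of each wild-type sample is not among its labels. Sequencing platform is confounded with strain, and galactose medium with overexpression of the factors. Nothing in the labels says whether the replicates are separate cultures, so the limma and exact permutation p-values below measure only the spread between these samples. The rotation and binomial p-values compare places in the genome and hold no spread between samples.

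The authors fitted fork paths to the strand-specific fragment counts of each sample and deposited 3 tables per sample. The aligner, the genome build and the fitting program are not given in the sources used here, and the per-base fragment counts were not analysed here. The first deposited table lists line segments of rightward and leftward forks, each with its start and end in bases and in minutes and with its probability as a fraction from 0 to 1. Every longer segment has the same slope, 2900 bases per minute, so fork speed is a constant of the authors' fit and not a measurement. The second deposited table samples these segments along the chromosomes, with times in minutes and probabilities as a fraction. The third gives the probability-weighted mean time of each position at steps of 500 bases, in minutes as deposited by the authors, with the summed probability, a fraction that is 1 throughout. The lowest mean time is 0 in each of the 5 samples, so time 0 is the earliest averaged position of that sample and not the start of S phase. The weighted means were recomputed from the sampled paths and differed from the deposited ones by at most 0.000537 min in any sample. The files hold no read counts, so the depth of each sample is unknown and no interval that needs it was computed.

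Mean time and the share of probability in rightward forks were averaged in 2386 windows of 5 kb that hold at least 50% of their positions in all samples. An initiation site is a place where a rightward and a leftward segment start together with a probability of at least 0.1. Sites of different samples within 2500 bp were joined, which gave 407 sites, and a sample with no site there was set to 0. The summed probability of all sites of a sample estimates the number of initiations per genome copy. Between adjacent sites of probability at least 0.3 in the same sample, the termination position was taken where the rightward share falls through 50%. A termination event is a place where a rightward and a leftward segment end together.

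Windows and sites were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 groups, all 5 samples, 2 residual degrees of freedom), two-sided, with the Benjamini-Hochberg threshold at 0.05. The lone glucose sample is assumed to vary like the other groups. Neighbouring windows share forks and are not independent. Values per sample were compared with two-sided exact permutation tests of the 2 galactose samples against the other 3, where the smallest possible p is 0.1. Galactose against glucose alone cannot go below 0.333. Sets of windows were tested by 10000 circular rotations of the window series along the genome, two-sided, with Benjamini-Hochberg adjustment over the 2 sets. Counts of sites with a neighbour within 10 kb were set against the share of genome positions that have one, among positions over 2500 bp from any such site, with a two-sided exact binomial test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

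The comparisons, their tests, the rule for named items, the region lists and most alternatives were set before the data were examined. The rule names the 10 regions and 10 sites with the largest change in each direction between galactose and glucose, and the 3 largest between glucose and wild type. Both galactose samples had to lie on the same side of glucose, and for sites the gap to the nearer one had to exceed the gap between them. A region is a run of adjacent windows past the threshold. Counts of shared and private sites, distances to neighbouring sites, the grouping of sites by wild-type probability or start time, sums near chromosome ends and the share of strong termination events were chosen after the data had been seen. Of 14 region lists, 2 could be placed from the files alone, the 30 kb at each chromosome end and the 50 kb on each side of the gap on chromosome XII. The other 12, the named origins and the loci of the 6 factors were not tested, since the build is not given. Coordinates are therefore those of the files, with no gene or origin names.

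The pipeline was tested on simulated data for galactose against glucose. Its noise was independent and normal, with 1 SD taken from the replicates (3.91 min for all windows and 0.119 for all sites). Of 200 changed windows among 2386, shifts of 5, 10 and 20 min were recovered in 0%, 0.5% and 87.5%. Of 200 changed sites among 407, changes of 0.25, 0.5 and 1 were recovered in 6%, 83% and 100%. Calls among unchanged windows numbered 0, 0 and 5, and among unchanged sites 1, 3 and 10. Real windows share forks and real site probabilities are bounded at 0 and 1, so these rates need not hold for the real data. Alternatives covered the window size, times centred on the median or ranked within a sample, a trend in limma's spread, recomputed times, positions left out, the site minimum, the joining distance, the measure and scale of site probability, the termination minimum, the form of the rotation test and leaving out each replicate. Profiles without chromosome IV, joining within 10000 bp and some left-out replicates were added after the data had been seen.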

Results

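Okazaki fragments, the short pieces of the lagging strand, show which way forks move through each part of the genome and so where replication starts and stops. In this assay doxycycline represses DNA ligase I, so the fragments stay unjoined. The data are 5 fitted replication profiles of budding yeast in 3 groups: galactose (n = 2, samples E and G), glucose (n = 1, sample F) and wild type (n = 2, samples A and B). The galactose and glucose samples are 1 strain, in which galactose induces 6 initiation factors. Of these, Sld3, Sld7 and Cdc45 act on the loaded helicase, Sld2 and Dpb11 bring in further helicase subunits, and Dbf4 activates the Cdc7 kinase. Galactose against glucose asks how replication changes when the 6 factors are raised, and glucose against wild type asks how far the strain without induction resembles its parent. Read depth is unknown, since the files hold no counts, and the fits of galactose E and G hold 3345 and 3189 segments, those of glucose F 4545 and those of wild type A and B 6353 and 6039.

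Fork direction was alike within each replicated group, while replication time varied more. Across 2386 windows of 5 kb, Pearson's r of the rightward share was 0.933 between galactose E and G and 0.929 between wild type A and B. For time it was 0.631 and 0.721, and replicates differed by a mean of 3.93 and 3.78 min. Glucose resembled wild type in fork direction (r = 0.884 with A and 0.859 with B), and galactose differed from glucose and wild type alike (r from 0.677 to 0.714). Galactose E and G shared 308 of 347 sites, and wild type A and B shared 266 of 325. These correlations are across windows of the genome, which are not independent replicates.

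Cells overexpressing the 6 factors used their initiation sites more on average. Galactose E and G held 316 and 339 initiation sites, against 277 in glucose F and 282 and 309 in wild type A and B. Summed over sites, this came to 261 ± 16.1 initiations per genome copy in galactose (SD, n = 2), against 182 in glucose and 175 ± 12.6 in wild type (SD, n = 2), or 1.43 and 1.49 times as many. The mean probability of a site was 0.796 ± 0.00978 in galactose, 0.657 in glucose and 0.593 ± 0.00429 in wild type. Sites that fired in at least 90% of copies numbered 121 and 165 in galactose, 51 in glucose, and 15 and 37 in wild type. On average 48.4 and 44.3 kb of genome fell to each initiation in galactose, against 66.3 kb in glucose and 72.6 and 65.6 kb in wild type. The exact permutation p of galactose against the other 3 was 0.1 for the summed probability, the smallest that this design allows, and 0.2 for the number of sites. Of 24 such measures per sample, 16 reached it, and the lowest adjusted p was 0.15.

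**Figure D1:**
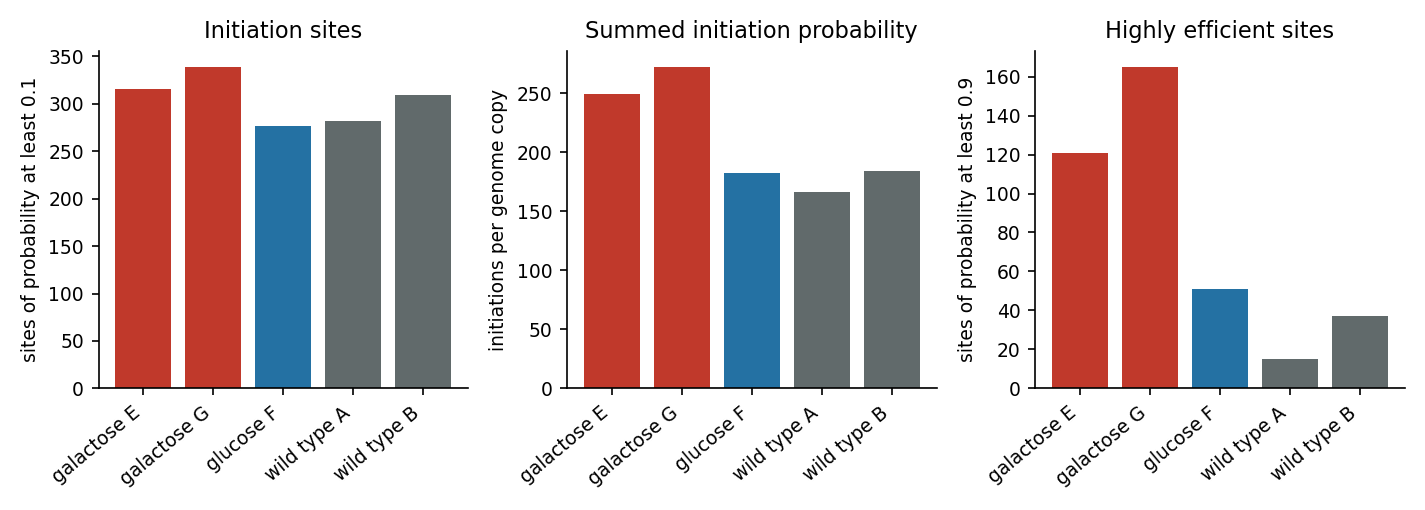
Bars give, for each sample, the number of initiation sites of probability at least 0.1, their summed probability (initiations per genome copy) and the number of sites of probability at least 0.9. Galactose E and G reach 249 and 272 initiations, above the 166 to 184 of the other 3 samples.

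The higher use of sites was spread over the whole genome. On each of the 16 chromosomes, the summed probability of both galactose samples lay above that of all 3 other samples. The ratio of galactose to glucose ran from 1.24 on chromosome IX to 1.71 on chromosome II. Near chromosome ends it was larger, since sites within 30 kb of an end summed to 14.9 and 15.4 in galactose, 6.60 in glucose, and 9.66 and 8.97 in wild type. That is 2.30 times glucose at the ends and 1.40 times elsewhere, but 1.63 and 1.48 times wild type, so the excess at ends is smaller against wild type. These ratios were not tested.

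Site by site, 100 of 407 sites were used more in galactose than in glucose, with a median gain in probability of 0.585, and they lay on all 16 chromosomes. Of these, 51 were listed in both groups and 49 were not listed in glucose. A glucose site lay within 10 kb of 11 of the 49 (22.4%, against 38.0% of comparable genome positions; exact binomial p = 0.0268, adjusted p = 0.0535 over 2 such tests). Some went from 0 in glucose to nearly every cell: on chromosome X at 654490 both galactose samples reached 1 (adjusted p = 0.00322 by limma). On chromosome VIII at 212336 they reached 0.959 and 1 (adjusted p = 0.00332), and on chromosome VII at 917204 they reached 1 and 0.915 (adjusted p = 0.00571). These 3 sites were listed in neither wild-type sample. The sites on chromosome II at 93764, chromosome XII at 51893 and chromosome XIV at 28457 were weak in wild type (0.115 to 0.304) and stood at 0.905 to 1 in galactose. On chromosome XV at 308985 wild type stood at 0.675 and 0.585, glucose at 0 and both galactose samples at 1. In the remaining 3 of the 10 largest gains, a glucose site lay 2.78 to 5.01 kb away: on chromosome I at 124486, chromosome VIII at 168762 and chromosome XVI at 117154. Joined with that site within 5000 bp, their gains of 0.985, 1 and 1 were 0.709, 0.470 and 0.240, and the last 2 are loci that also count among the losses, as VIII at 171539 and XVI at 122161. Adjusted p over these 10 sites ran from 0.00322 to 0.0103.

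In limma, 120 sites passed in all, 100 higher and 20 lower, and 166 had an unadjusted p under 0.05. Both galactose samples lay above all 3 others at 210 sites and below all 3 at 11, where the mean over all 10 ways to split the samples 2 against 3 is 8.28% and 6.90% of sites. The galactose pair is 1 of these 10. Among the other pairs the highest count was 30 above, and 106 below for wild type A and B. The 100 higher sites were 62 when wild type A or B was left out. The 20 lower sites were 31 when joined within 1000 bp, 12 within 5000 bp, 10 within 10000 bp and 13 by the rise of the rightward share. At 14 called sites, 1 higher (X at 654490) and 13 lower, replicates were identical because they stood at 1 or were set to 0, so the p there rests on the spread limma pools over sites.

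**Figure D2:**
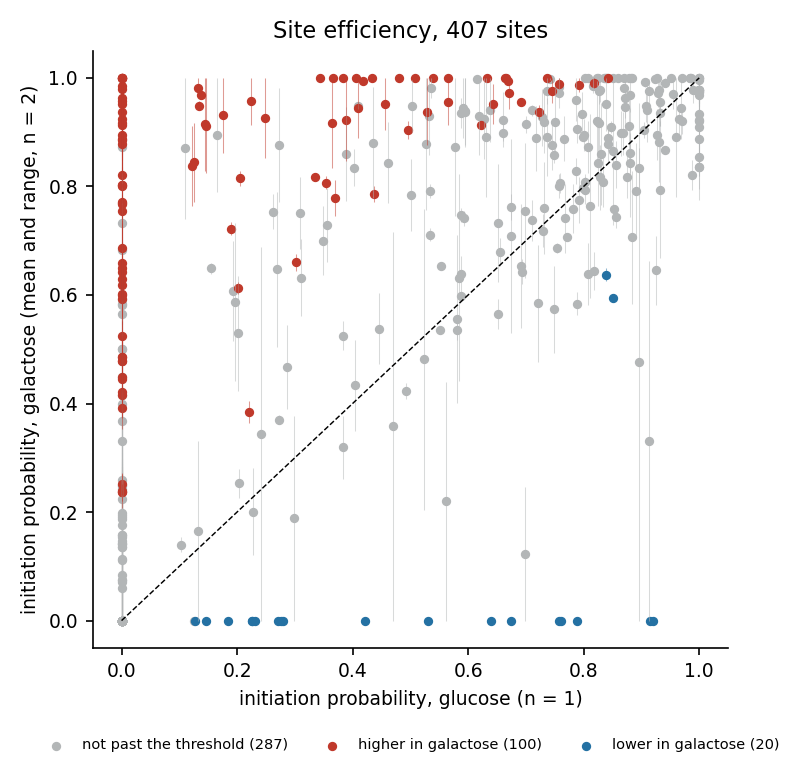
Each point is 1 of 407 sites, with its initiation probability in glucose (n = 1) on the x axis and the mean of the 2 galactose samples on the y axis; thin lines give their range, and the dashed line marks equal values. The 100 sites higher in galactose by limma lie far above the line, 49 of them at 0 in glucose.

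Weak sites differed most. Among 266 sites listed in both wild-type samples, the quartile with the lowest wild-type probability stood at a mean of 0.652 ± 0.0448 in galactose (SD, n = 2), 0.272 in glucose and 0.308 in wild type. In the strongest quartile the means were 0.8996 ± 0.0207, 0.868 and 0.882. The ratio of galactose to glucose was 2.40, 1.3, 1.08 and 1.04 from the weakest quartile to the strongest. By start time in wild type it was 1.19, 1.20, 1.24 and 1.47 from the earliest quartile to the latest. The ratio of galactose to wild type in the same quartiles was 1.21, 1.275, 1.297 and 1.293, with no such rise in the latest. There the glucose mean, 0.516, lay below the wild-type mean, 0.585. Probability cannot exceed 1, which limits how far strong sites can differ.

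A group of 35 sites was listed in both galactose samples and in none of the other 3. Some lay beside a site that both galactose samples lacked, so shifted positions may be among the 35. For example, VII at 568376 was 3.29 kb from 571666, and IV at 550956 was 4.19 kb from 555144. The 35 sites lay on 14 chromosomes, with a mean probability of 0.597 in E and 0.644 in G. Sites of 1 galactose sample alone were fewer and weaker, 3 in E (mean 0.306) and 17 in G (mean 0.363). In contrast, 228 sites were listed in all 5 samples, with means of 0.849 and 0.883 in galactose, 0.710 in glucose, and 0.634 and 0.686 in wild type. These groups were counted without a test.

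Sites that were lower in galactose were mostly absent there, and many had a galactose site close by. Of the 20 lower sites, 18 were listed in neither galactose sample, and 11 of these 18 had a site of both galactose samples within 10 kb. That is 61.1%, against 42.4% of comparable genome positions (exact binomial p = 0.151, adjusted p = 0.151), so no excess over position alone was shown. Among the 10 largest losses 9 had such a site. Chromosome XV at 490333 went from 0.914 in glucose (0.723 and 0.652 in wild type) to 0, with a galactose site 6.50 kb away (adjusted p = 0.00548 by limma). Chromosome XII at 231184 went from 0.788 to 0 with a galactose site 8.96 kb away, chromosome IV at 555144 from 0.757 to 0 with one 4.19 kb away, and chromosome XVI at 379132 from 0.674 to 0 with one 5.54 kb away. The exception was chromosome IV at 463166, with 0.699 in glucose, 0.841 and 0.871 in wild type, and 0.247 and 0 in galactose. Its nearest other site was 20.9 kb away, and its adjusted p was 0.0677 against glucose and 0.0240 against wild type. The other 5, on chromosome I at 24848, XVI at 122161, VI at 63897, VIII at 171539 and XI at 646080, were listed in glucose alone (0.422 to 0.920), with a galactose site 2.78 to 5.01 kb away. Joining sites within 5000 bp turned 4 of these 5 into gains of 0.240, 0.239, 0.470 and 0.333; the site on chromosome I at 24848 is not among them.

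Without induction, the strain resembled wild type in how often sites were used. Across sites, Pearson's r of the probability of glucose F was 0.850 with wild type A and 0.803 with B, against 0.535 to 0.644 between galactose and the other 3 samples. The list of sites did not set glucose apart, since glucose shared 78.6% and 69.9% of sites with wild type A and B, and galactose E and G shared 74.9% and 70.2% with glucose. Between glucose and wild type, 12 of 407 sites passed in limma, 8 higher and 4 lower in glucose, and 96 had an unadjusted p under 0.05. The 3 largest gains, on chromosome I at 24848 (0.920), XVI at 122161 (0.760) and VI at 63897 (0.639), each had a site of both wild-type samples 4.55 to 5.01 kb away. The 3 largest losses went to 0 in glucose. Chromosome VII at 571666 stood at 0.607 and 0.656 in wild type (adjusted p = 0.0239) and at 0 in galactose too, with a galactose site 3.29 kb away. Chromosome XIV at 563991 stood at 0.782 and 1 in wild type (adjusted p = 0.0822), and chromosome XVI at 881081 at 0.574 and 0.770 (adjusted p = 0.128), and neither passed. Glucose had another site 2.81 kb from the latter, at 0.271. limma gave 0 sites when they were joined within 5000 bp (78 at an unadjusted p under 0.05) or 10000 bp (79) or measured by the rise of the rightward share (80), 31 when joined within 1000 bp and 40 on the arcsine scale. Leaving out wild type A gave 91 calls, 56 of them lower, and leaving out B gave 71; leaving out galactose E or G gave 23, all higher.

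Galactose differed from wild type much as it differed from glucose. Of 407 sites, 146 were higher and 18 lower in galactose than in wild type, and 212 had an unadjusted p under 0.05. Of the 100 sites higher than in glucose, 95 were also higher than in wild type, against 35.9 if the lists were independent. Both contrasts use the same galactose samples. In simulated data with no effect this sharing alone gave a correlation of 0.413 between the contrasts, against 0.804 here. The 146 higher and 18 lower sites were 98 and 8 without galactose E, 79 and 3 without galactose G, 83 and 43 without wild type A, and 79 and 21 without wild type B.

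Replication time followed the wild-type order less steeply in galactose than in glucose. All times here and below come from the authors' fit to asynchronous cultures, with the same constant fork speed in every sample, and were not measured. Whether fork speed differed between samples, which would change these times, was not tested. Regressed on mean wild-type time, the slope was 0.223 in galactose E and 0.387 in G, against 0.828 in glucose. Between the wild-type samples it was 0.753 for B on A and 0.690 for A on B. The mean time of a window was 9.93 ± 1.17 min in galactose (SD, n = 2), 13.98 min in glucose and 13.3 ± 0.555 min in wild type. In the quartile of windows that is earliest in wild type, galactose minus glucose was 0.00432 ± 0.411 min (SD, n = 2). In the following quartiles it was -1.98 ± 0.754, -5.26 ± 1.49 and -8.93 ± 2.01 min. Against wild type the same quartiles gave 1.70, -1.87, -3.81 and -9.33 min in galactose, and 1.70, 0.107, 1.46 and -0.392 min in glucose. Each of these times counts from the sample's own time 0: with each sample centred on its median, galactose minus glucose was 3.02, 1.03, -2.25 and -5.92 min by quartile, and galactose minus wild type 5.74, 2.16, 0.231 and -5.29 min. Quartiles chosen on wild-type time also draw any other sample toward the mean, so glucose on the same quartiles is the measure to compare with. Slopes do not depend on the zero. The change of galactose against glucose had a slope of -0.523 min per min of wild-type time (-0.605 in E and -0.441 in G), negative on 15 of 16 chromosomes. By chromosome means, both galactose samples were earlier than glucose on 11 of 16 and earlier than all 3 others on 9. On chromosome VII galactose E stood at 11.5 min, G at 19.7 min and glucose at 12.3 min. The galactose mean there was 3.29 min later than glucose, through G alone. The exact permutation p of mean time against the other 3 samples was 0.1, the smallest possible. Without chromosome IV the difference in mean time from glucose was -2.47 in place of -4.04 min.

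The spread of replication time was narrower in galactose than in glucose. The SD over windows was 5.13 and 7.15 min in galactose E and G, 9.48 min in glucose, and 6.75 and 7.05 min in wild type. The span from the 5th to the 95th percentile was 17.5 and 23.9 min in galactose, 34.6 min in glucose, and 22.4 and 23.2 min in wild type. Galactose G lies above both wild-type samples in both measures, and against the other 3 samples together the exact permutation p was 0.6 for both. The interquartile range was 6.62 and 8.73 min in galactose, 9.98 min in glucose, and 8.97 and 9.42 min in wild type. The SD of site start times was 4.21 and 6.53 min in galactose, 9.10 min in glucose, and 6.91 and 7.24 min in wild type. For these 2 measures the exact permutation p was 0.1, the smallest possible. Chromosome IV carries most of the difference from glucose, which is -3.34 min in SD with it and -0.531 min without it, and -13.9 and -1.304 min in span.

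**Figure D3:**
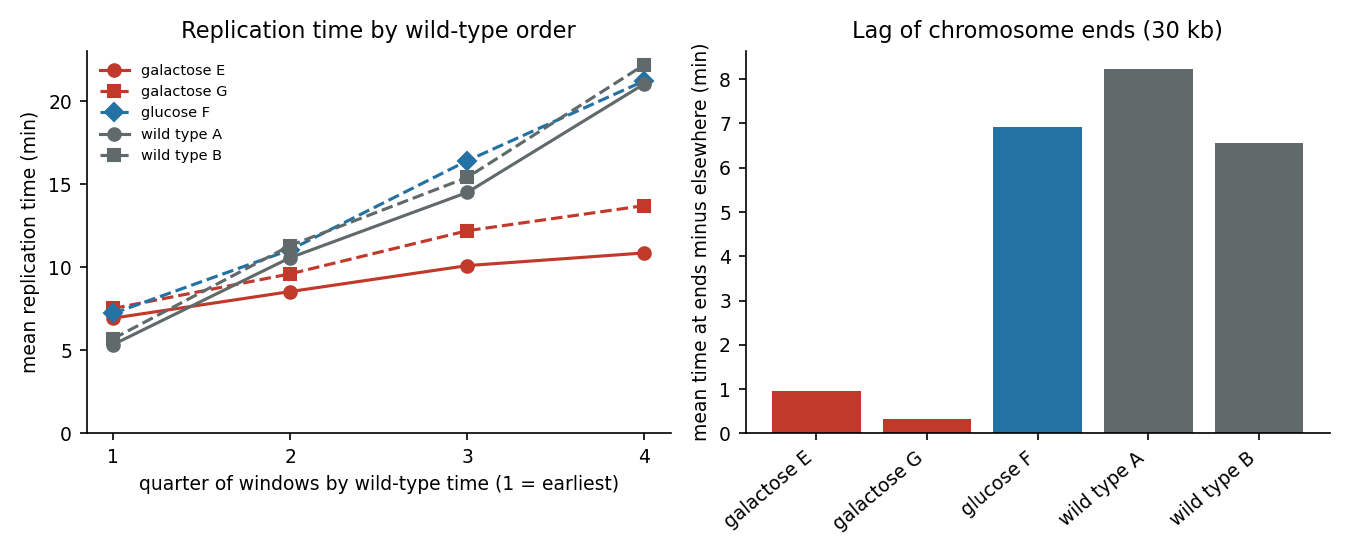
Left, the mean replication time (min) of each sample in quartiles of windows ordered by wild-type time; right, how much later (min) the 30 kb at chromosome ends replicate than the rest of the genome. In the latest quartile galactose E and G stand at 10.9 and 13.7 min and the other 3 samples at 21.04 to 22.2 min.

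Regions that were earlier in galactose than in glucose lay mainly at chromosome ends and on the right of chromosome IV. limma called 182 windows earlier and 0 later, in 10 regions on 7 chromosomes (910 kb), and 9 of the 10 regions reach within 30 kb of an end. The region on chromosome IV is 1 of these 9 and holds 112 of the 182 windows. Within 30 kb of an end lay 48 of the 182. On chromosome II, bases 745001 to 810000 had fitted times of 4.65 ± 0.283 min in galactose (SD, n = 2), 28.1 min in glucose and 23.6 ± 4.26 min in wild type. On chromosome VII, bases 1045001 to 1080000 stood at 8.32 ± 1.78, 27.7 and 30.9 ± 0.699 min. On chromosome XIV, bases 705001 to 780000 stood at 4.83 ± 0.544, 21.1 and 17.8 ± 0.547 min. The exception away from ends was chromosome XI, bases 565001 to 595000, at 4.54 ± 0.171, 18.1 and 14.2 ± 0.140 min. The other end regions were chromosome II 1 to 30000, VI 1 to 40000, VI 250001 to 270000, X 1 to 25000 and XI 635001 to 665000, where galactose was at 1.88 to 12.2 min and glucose at 17.7 to 31.3 min. In these 5 the wild-type mean ran from 16.4 to 26.1 min.

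The longest region was 560 kb on the right of chromosome IV, bases 965001 to 1525000. It replicated at 14.05 ± 0.485 min in galactose (SD, n = 2), 14.5 ± 1.20 min in wild type and 38.2 min in glucose, so glucose alone was late there. Of the 182 windows, 89 were also later in glucose than in wild type, and 52 were also earlier in galactose than in wild type. Counting windows without a threshold, both galactose samples were earlier than glucose in 57.5% and later in 23.8%, a balance that moves with the time 0 of each sample. Of 2386 windows 631 had an unadjusted p under 0.05. The call did not hold in every form: limma gave 0 windows without chromosome IV (431 at an unadjusted p under 0.05), 0 for times ranked within each sample (440) and 0 when galactose E (657), galactose G (575), wild type A (643) or wild type B (643) was left out. Centring each sample on its median gave 109, all earlier (417 earlier and 123 later at an unadjusted p under 0.05), and 6 of the 10 regions lost the call, with differences from -21.1 to -10.5 min over the 10.

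**Figure D4:**
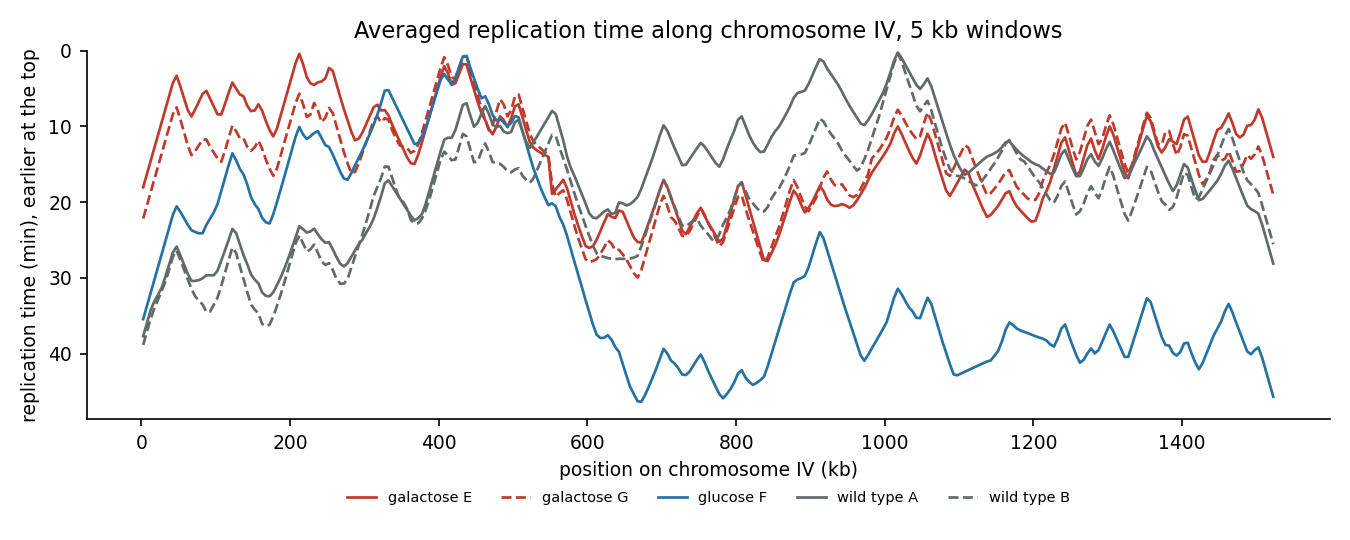
Replication time (min, earlier at the top) in 5 kb windows along chromosome IV, 1 line per sample. Right of about 600 kb, glucose F lies below the other 4 samples, and in bases 965001 to 1525000 it averages 38.2 min.

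Glucose was later than wild type on chromosome IV and nowhere else past the threshold. All 90 called windows lay there in 4 regions (450 kb), and 364 windows of the genome had an unadjusted p under 0.05. The 3 largest were bases 960001 to 1250000 at 37.8 min in glucose and 11.7 ± 1.59 min in wild type (SD, n = 2), 1260001 to 1325000 at 39.1 and 16.6 ± 2.92 min, and 1375001 to 1450000 at 39.5 and 17.8 ± 0.237 min. Galactose against wild type gave 186 windows, all earlier in galactose, in 16 regions on 9 chromosomes, and 715 had an unadjusted p under 0.05, 576 earlier and 139 later, a balance that also moves with time 0. Of these 16 regions, 7 reach within 30 kb of an end. The longest region was the left end of chromosome IV, bases 1 to 280000, at 9.41 ± 3.604 min in galactose and 29.6 ± 1.65 min in wild type, with glucose at 19.3 min; it was singled out after its values were seen. In limma both counts were 0 without chromosome IV (100 for glucose and 565 for galactose at an unadjusted p under 0.05), on the rank scale (191 and 655), and when galactose E (386 and 594), galactose G (386 and 572), wild type A (490 and 707) or wild type B (273 and 621) was left out. Galactose against wild type was also 0 after centring (620) or with a trend in the spread (708), and glucose against wild type gave 175 after centring and 119 of 2012 windows without ends and chromosome XII.

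Chromosome ends were hardly later than the rest of the genome in galactose. The 30 kb at each end replicated at 10.0 and 11.1 min in galactose E and G, 20.4 min in glucose, and 20.5 and 19.7 min in wild type. They lagged the rest of the genome by 0.963 and 0.329 min in galactose, 6.92 min in glucose, and 8.23 and 6.57 min in wild type. The median of galactose minus glucose over 184 end windows was -9.46 min, and of the 48 of them past the threshold each was earlier. In 10000 rotations the permutation p was 0.0052 (adjusted p = 0.0104 over 2 lists), which compares places in the genome and not samples. Beside the 64.0 kb gap on chromosome XII, which carries the ribosomal DNA, the median change was 0.959 min over 21 windows (permutation p = 0.572), so no change was shown there.

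Many stretches of the genome were copied from the other side in galactose. Of 2386 windows, 292 (12.2%) changed their rightward share between glucose and galactose, 147 up and 145 down, with a median change of 0.516. In 196 of the 292 the main direction reversed. Windows in which over 90% of forks ran 1 way made up 46.8% and 52.5% in galactose, 40.8% in glucose, and 23.2% and 30.6% in wild type. Between galactose and wild type 457 windows passed, and between glucose and wild type limma gave 0, with 432 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0862 (95 of 11928 windows of 1 kb passed). For galactose against glucose 735 had an unadjusted p under 0.05. Without galactose E or G limma gave 0 windows (631 and 597 at an unadjusted p under 0.05).

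Forks met closer to the midpoint between sites in galactose. Between adjacent sites of probability at least 0.3, the median distance of the termination position from the midpoint was 4.60% and 4.32% of the interval in galactose E and G. It was 10.7% in glucose, and 9.73% and 11.1% in wild type. Within 10% of the midpoint lay 76.3% and 79.0% of terminations in galactose, 45.9% in glucose, and 53.3% and 46.8% in wild type. Termination was also more focused, with 71.4% and 75.3% of its probability in events of at least 0.5 in galactose, 49.8% in glucose, and 27.5% and 36.1% in wild type. The intervals numbered 285 and 303 in galactose, 219 in glucose, and 223 and 234 in wild type. The offsets rest on those where the rightward share falls through 50% once. These numbered 270 and 286 in galactose, 194 in glucose, and 197 and 203 in wild type. Intervals with no such fall numbered 14 and 16 in galactose, 24 in glucose, and 22 and 29 in wild type. Termination position had no test by design. Its relation to the difference in start time of the flanking sites (Pearson's r from 0.864 to 0.951 across intervals) follows in part from the constant fork speed of the fit.

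**Figure D5:**
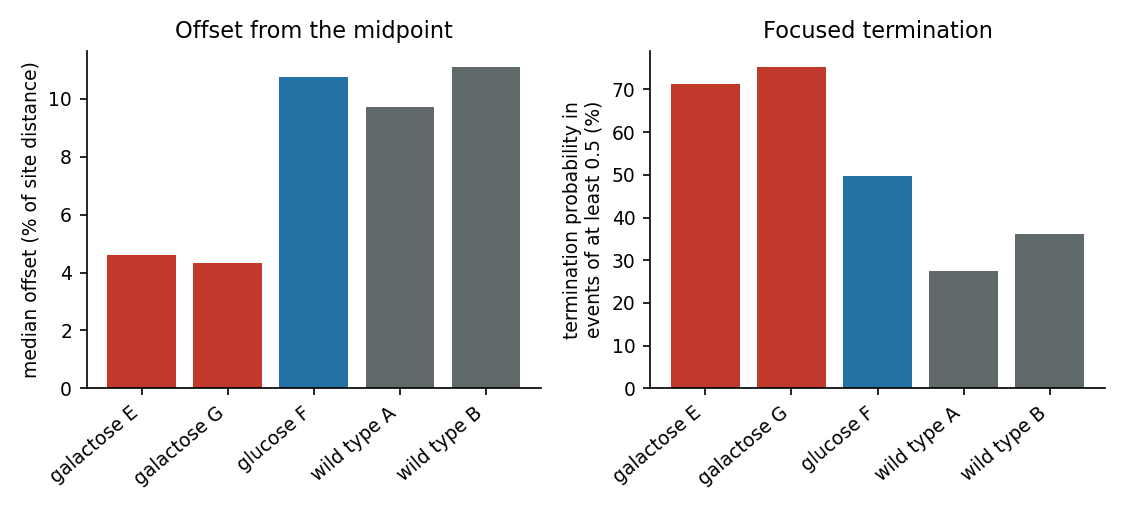
Bars give, per sample, the median distance of termination from the midpoint between adjacent sites (% of the interval) and the share of termination probability in events of at least 0.5 (%). Galactose E and G have the smallest offsets, 4.60% and 4.32%, and the largest shares, 71.4% and 75.3%.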

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

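Leaving out chromosome IV, joining sites within 10000 bp and leaving out galactose replicates for site number, termination and chromosome ends were chosen after the data had been seen. Across all alternatives run, the summed initiation probability stayed 1.37 to 1.496 times that of glucose, chromosome ends stayed earlier than in glucose or wild type (-12.0 to -9.37 min), and termination offsets stayed lower by -6.43 to -6.14 percentage points. Site calls of galactose against glucose stayed between 20.1% and 31.8% of sites. The cause was not tested for any shift below. Without chromosome IV, mean time against glucose moved to -2.47 min, its SD to -0.531 min, its span to -1.304 min, and windows called by limma to 0% in all 3 contrasts. Ranking also gave 0% in all 3, and a quartile slope of -0.379. Centring gave 4.57% for galactose against glucose, 7.33% for glucose against wild type and 0% for galactose against wild type, and a trend in the spread gave 0% for the last. Without ends and chromosome XII, glucose against wild type gave 5.92%. Leaving out a replicate, which leaves 1 residual degree of freedom, gave 0% to 0% of windows in each contrast, 0% to 9.64% for fork direction and slopes of -0.605 to -0.392. Site calls of glucose against wild type went from 2.95% to 6.64% (joined within 1000 bp), 0% (5000 bp, 10000 bp, or the rise of the rightward share), 9.83% (arcsine scale) and 5.65% to 22.4% (1 replicate left out), where without wild type A, at 22.4%, most were lower. Counting sites of at least 0.2 moved the ratio of site number from 1.18 to 1.26. Among named sites, 4 turned from loss to gain when joined within 5000 bp: XVI 122161 (0.240), VI 63897 (0.239), VIII 171539 (0.470) and XI 646080 (0.333); joining counts the neighbouring site with them. Of the alternatives for named sites 194 kept direction and call, 33 lost the call and 3 gained it; for named regions 42 kept both and 75 lost the call. Of these 75, 52 left out a replicate, where the differences stayed at 88.7% to 111% of their size. Depth is unknown, so what it limits cannot be stated.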

Other observations

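Tests of sequencing platform, weaker signal, galactose medium and edge effects were chosen only after the result was seen. Sites listed in wild type and dropped elsewhere formed a small group. There were 12 sites listed in both wild-type samples and in no sample of the other strain, on 9 chromosomes, with mean probabilities of 0.359 and 0.334. Of these 12, 6 lay within 30 kb of a chromosome end, against 43 of all 407 sites. A further 14 sites on 10 chromosomes were listed in wild type and galactose but not in glucose, at 0.371 and 0.365 in wild type and 0.858 and 0.871 in galactose. Another 5 sites were listed in glucose and both wild-type samples and in neither galactose sample, and 13 in glucose alone. Some of the 14 lie beside some of the 13. VIII at 168762 and XVI at 117154 are 2.78 and 5.01 kb from the glucose-only sites at 171539 and 122161. The join of 2500 bp keeps such neighbours apart, so these counts partly record shifted positions or split loci.

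Except in glucose, the fitted start time of a site was only weakly related to its probability. Fitted times differ between replicates by long offsets along chromosomes, so a weak relation here cannot show that timing and use are unrelated. Across sites within a sample, which are not independent replicates, Spearman's rho of start time with probability was -0.0147 and -0.0598 in galactose E and G, -0.263 in glucose, and -0.121 and -0.0146 in wild type. In glucose the earliest quartile of sites had a mean probability of 0.736 and the latest 0.560. Mean termination time was 11.8 and 13.2 min in galactose, 16.7 min in glucose, and 15.8 and 16.4 min in wild type. Chromosome means of time differed between replicates, with chromosome VII at 11.5 min in galactose E and 19.7 min in G, and chromosome XIV at 5.96 and 13.5 min.

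The higher summed initiation probability in both galactose samples was weighed first. Sequencing platform is argued against for this sum, since glucose was read like galactose and covered 7.91% of the gap between wild type and galactose. The sum joins fewer sites in glucose (277, against a wild-type mean of 295.5) with a higher mean probability. By mean probability of a site, glucose stood 0.0642 above the wild-type mean and galactose 0.204. By the share of windows with over 90% of forks 1 way, glucose stood 13.9 percentage points above the wild-type mean and galactose 22.7. For that share, platform is not argued against. A weaker signal that lowered every site in glucose by 1 factor is argued against as well: its strongest quartile of sites had a mean of 0.868, above the 0.730 that such a factor allows. A weaker signal that lowered or dropped mainly weak sites was not tested and stays open, since depth is unknown. Overexpression of the 6 factors may account for the rise, as a hypothesis. Galactose medium itself cannot be told apart from it, since 0 samples without the inducible factors are labelled with galactose.

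Glucose alone was late on the right of chromosome IV, by 23.7 ± 3.56 min against wild type (SD over windows). A loss of sites is argued against, since the summed site probability there was 1.08 times that of wild type. An offset that the fit carried along the chromosome may account for it: fork direction inside the block differed from wild type by 0.0937, at percentile 7.25 of 690 other stretches of its length (median 0.122). Start times of sites against wild type were -13.99 to -7.67 min from 46407 to 435219, -3.54 min at 505694, 14.9 min at 555144 and 19.97 min at 628592. A real delay of that arm in this culture stays open and was not tested. Long offsets in start time also separated replicates. On chromosome VII from 17747 to 508882, sites started at 4.85 to 9.93 min in galactose E and 20.4 to 25.2 min in G.

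Chromosome ends that kept little delay in galactose were weighed last. If ends had only moved like other late windows, their shift would match windows of the same wild-type time; it went -3.34 min beyond them (95% of rotations from -3.07 to 2.86 min), although matched windows account for -6.49 of -9.83 min. An edge effect of equal size in all samples is argued against as the whole cause, since the lag of ends was -6.59 min lower in galactose than in the other 3 (their SD 0.878). That all samples were fitted with the same settings is assumed. An edge effect that varies with the sites near an end was not tested. A stronger effect of the raised factors near ends and an effect of galactose medium stay open and were not tested.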
